A study of Mus musculus with 11 samples.

How the data were processed

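Spleen cells from mice were sorted by fluorescence-activated cell sorting into 3 groups of P14 CD8 T cells, which carry a transgenic T cell receptor for an epitope of lymphocytic choriomeningitis virus (LCMV). The groups were naive cells at day 0 (3 arrays), and CD25lo and CD25hi effector cells at day 3.5 after LCMV infection (4 arrays each). Per the labels' protocols, RNA was extracted with Trizol, amplified through 2 rounds of cRNA synthesis, labelled with biotin and hybridised to Affymetrix mouse 430.2 arrays. The labels call the arrays biological replicates. They do not say whether each came from a separate mouse, so p-values measure the spread between these samples.

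The deposited values are log2 expression values made with RMA, per the submitters' processing notes, which give no version. The table held 45037 probe sets on 11 arrays, and 0 columns belonged to no sample here. Every probe set had a median of exactly 0 over the 11 arrays, so each had been centred on its own median. Differences between arrays within a probe set were kept by this step, while absolute signal levels, and with them signal over background, were lost. The log2 scale was read from the values. Their floating-point step matched differences between numbers from 2 to 16, and the largest range within a probe set was 9.44. The same step gave a coarse class of each probe set's level before centring. It was 8 or more for 16997 probe sets, 4 to 8 for 21339 and under 4 for 6701. On simulated values this rule put 91.2% of probe sets into the right class. Those values had the same spread on all arrays and no group differences, unlike the real ones. The rule asked that a share of 0.7 of a probe set's values fit the step, so a dim probe set can be classed too high by chance. Array medians lay between 0 and 0.0393 except in naive replicate 3, where the median was 0.133. Scan dates and batches were not given in the sources used here.

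Gene names came from the platform annotation matched to the current mouse gene table by Entrez identifier. It named 1 gene for 34945 probe sets, several genes for 932 and was not used for 9160 unlisted ones. The symbols needed no update, and 204 probe sets had an identifier outside the gene table. Some genes are not reported here. A gene's value was the mean of all probe sets naming that gene alone, which gave 18193 genes, 9010 of them with several probe sets. The plan had been to take the probe set with the highest mean level. Because centring removed the levels, the mean of probe sets, planned as an alternative, took its place.

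Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with default settings). The 11 arrays entered 1 fit with a mean per group, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The 3 comparisons were CD25hi with CD25lo, CD25lo with naive and CD25hi with naive. A change is called where its adjusted p passed that threshold, and errors of log2 differences are standard errors (SE) from this fit. The spread between naive arrays was wider than between effector arrays, with a median SD over probe sets of 0.246 for naive, 0.0976 for CD25lo and 0.0948 for CD25hi. Only the number of arrays limits the precision that can be stated, since array values carry no counts. On simulated data with the real spreads, 200 changed genes among 18193 were tested for CD25hi against CD25lo. The fit recovered 60.6% of 66 genes changed by 0.5 on the log2 scale, 94% of 67 changed by 1 and 100% of 67 changed by 2, with 3.08% of calls false. A fit of only the CD25hi and CD25lo arrays recovered 84.8%, 100% and 100%, with 6.17% of calls false (14 false calls). This was 1 simulation, which cannot tell that share from the 5% that the threshold allows on average.

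Before the data were examined, 24 gene lists were fixed. They were cytotoxic effector molecules, terminal effector markers, memory precursor and naive-associated genes, IL-2 and STAT5 responsive genes, S phase, G2 and mitosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid transport and ribosome biogenesis, type I interferon response, TCR-induced early genes, inhibitory receptors, chemokines with homing and adhesion, apoptosis regulators, endoplasmic reticulum chaperones, and cytokine receptors. Markers of B cells, of macrophages with monocytes and dendritic cells, of neutrophils, of CD4 and regulatory T cells, of NK cells, and of erythroid cells with platelets formed 6 more, and sex-linked genes the last. Il2ra, which encodes CD25, was left out of every list because the sort used it. Lists were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 24 lists. An estimated correlation and fry, which tests whether a list moves on balance in 1 direction, were alternatives.

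Genes named in the text followed a rule fixed at the same time. It took a panel of 21 T cell genes, of which 18 were measured and named here, the 10 largest changes in each direction between CD25hi and CD25lo, and the 8 largest in each direction against naive. Those had to be called with groups that did not overlap, and unnamed transcripts and antigen receptor genes were passed over. It also took up to 4 called members of each list with the largest test statistic. Any other gene is said to have been chosen after its values were seen.

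The alternatives were a fit of only the groups compared, the replicate number as a block, centring each array on its median, the probe set with the largest interquartile range, leaving out probe sets that can match several transcripts, testing every probe set, an intensity trend with robust eBayes, array weights, and leaving out each of the 11 arrays in turn. Quantile normalization, a filter on mean level and an RNA quality covariate had also been planned. They were not run because the centred table carries no levels and no control probe sets. No array was a copy of another in its group, since at most 3.01% of values were identical (CD25hi replicates 3 and 4). Each array was counted as a sample, though this does not show that the arrays are independent.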

Results

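Gene expression was measured in sorted P14 CD8 T cells, mouse T cells that recognise LCMV, before infection and during early expansion. Naive cells gave 3 arrays, and effector cells at day 3.5 gave 4 CD25lo and 4 CD25hi arrays. CD25 is the alpha chain of the high-affinity receptor for interleukin-2 (IL-2). The labels present the CD25-defined subsets as a way to compare effector cells that die with those that give rise to memory cells. Along the leading principal component, with 82.4% of the variance, naive and effector arrays separated. The next, with 8.69%, separated CD25hi from CD25lo.

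The comparison of CD25hi with CD25lo asked how the effector subsets differed while both were expanding. Il2ra, the gene of the sorted protein, was 3.87-fold higher in CD25hi cells (log2 difference 1.95 ± 0.08 SE, n = 4 and 4, adjusted p = 9.21e-09), as the sort requires. Genes of naive and memory T cells were lower in CD25hi. Id3, an inhibitor of E proteins, was 11-fold lower (-3.46 ± 0.22), Il7r, the interleukin-7 receptor alpha chain, 2.34-fold lower (-1.22 ± 0.16), and the lymph node homing receptor Ccr7 2.99-fold lower (-1.58 ± 0.25). The transcriptional repressor Bcl6 was 2.45-fold lower (-1.29 ± 0.14), as the mean of probe sets at -2.39 and -0.187, of which 1 was called. Prdm1, which encodes the repressor Blimp-1, was 2.27-fold higher (1.18 ± 0.18), and Klrg1, a surface marker of terminal effectors, was 1.82-fold higher (0.87 ± 0.09).

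At an adjusted p under 0.05, 3674 of 18193 genes differed, 1670 higher and 2004 lower in CD25hi. Among these, 321 differed by 2-fold or more, 83 higher and 238 lower. The largest increases besides Il2ra were in Mt2, a metallothionein (5.19-fold), Dusp4, a phosphatase acting on MAP kinases (4.77-fold), Esm1 (4.46-fold), Dnph1 (4.01-fold) and Asns, asparagine synthetase (3.82-fold). Niban2, the arginine transporter Slc7a3, Msc and Cdh17 rose between 3.3-fold and 3.74-fold. The largest decreases were in Plbd1 (18.9-fold), Mpeg1 (13.9-fold), H2-Aa (11.2-fold), Nsg2 (11-fold), Id3, Dapl1 (9.87-fold), H2-Eb1 (9.29-fold), Cd74 (8.71-fold), Alox5ap (8.67-fold) and Rnase6 (8.61-fold). H2-Aa, H2-Eb1 and Cd74 belong to MHC class II antigen presentation, and dendritic cells in the CD25lo sort remain a candidate source of them. For the other large decreases too, bulk values do not show which cells made the transcripts. Each of these 20 genes had an adjusted p of 7.07e-06 or lower, and the 4 CD25hi arrays did not overlap the 4 CD25lo arrays.

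Of the panel genes, Il2rb, the beta chain of the IL-2 and interleukin-15 receptors, was 1.67-fold higher in CD25hi (0.74 ± 0.12). Gzmb, the protease granzyme B, was 1.45-fold higher (0.54 ± 0.11), and Ifng, interferon gamma, was 1.34-fold higher (0.42 ± 0.06). Il15ra was 1.22-fold lower (-0.29 ± 0.07) and Cd8a 1.31-fold lower (-0.39 ± 0.07), with 1 of 5 probe sets called and a range from -1.37 to 0.049. Cd44 (-0.07 ± 0.22), Tbx21 (-0.30 ± 0.22), Eomes (-0.28 ± 0.30), Id2 (0.19 ± 0.12), Prf1 (-0.13 ± 0.07) and Mki67 (-0.03 ± 0.10) were not called. In a fit of only the CD25hi and CD25lo arrays, Tbx21 (adjusted p = 0.00322), Eomes (adjusted p = 0.00142) and Id2 (adjusted p = 0.01) were called. The spread of the naive arrays does not enter that fit. In 1 simulation 6.17% of its calls were false, which cannot be told from the allowed 5%.

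**Figure D1:**
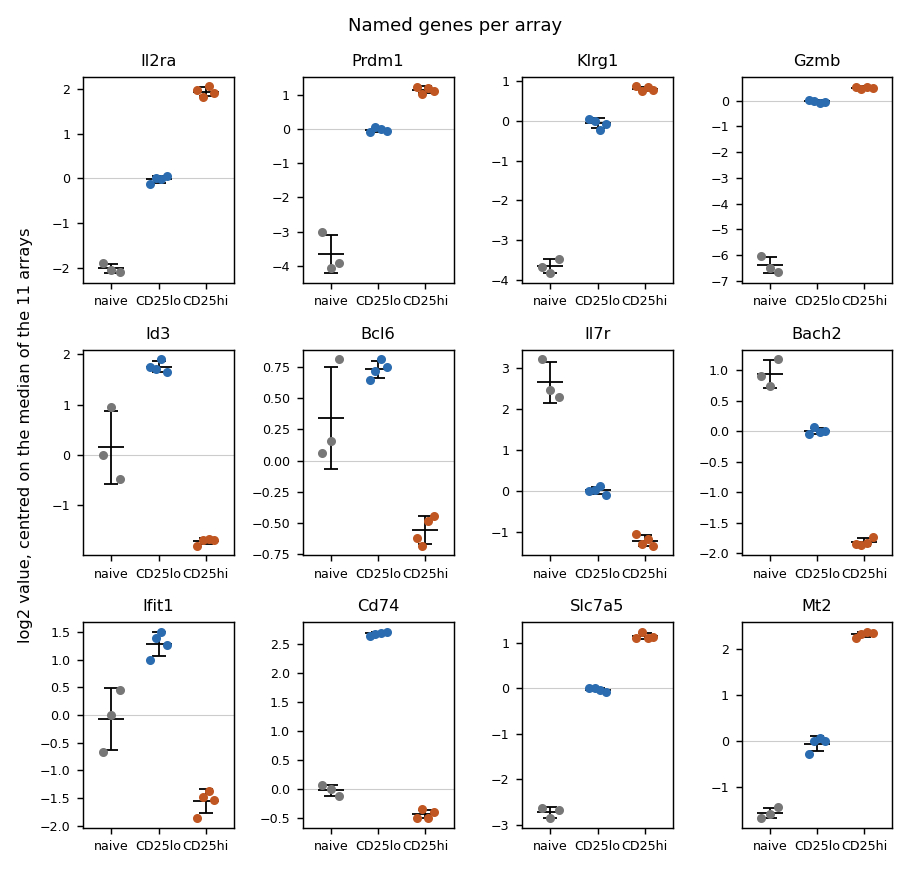
Values of 12 named genes on each of the 11 arrays, on the log2 scale centred on each gene's probe-set medians (vertical axis), by group (horizontal axis). Points are arrays, and bars show the mean and SD of 3 naive, 4 CD25lo and 4 CD25hi arrays. Id3, Bcl6, Ifit1 and Cd74 were highest on average in CD25lo, whereas Il2ra, Prdm1, Klrg1, Gzmb, Slc7a5 and Mt2 were highest in CD25hi.

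Memory precursor and naive-associated genes fell as a group in CD25hi. Of 24 measured members, 15 were lower and 1 higher (16 lower and 1 higher adjusted over the list alone), with a median log2 difference of -0.956 (camera adjusted p = 4.78e-13, or adjusted p = 0.00272 with an estimated correlation). Besides Id3, Dapl1 and Il7r, they included Bach2, a repressor that restrains effector differentiation (-1.82 ± 0.09), and the death receptor gene Tnfrsf25 (-2.14 ± 0.15). Bach2 probe sets ranged from -2.79 to -0.163. The list of terminal effector markers and regulators was not called (6 of 19 higher, 2 lower, 6 and 4 adjusted over the list alone, camera adjusted p = 0.485). Prdm1, Klrg1 and Havcr2 (0.96 ± 0.13) rose and Klrd1 fell (-1.02 ± 0.07). Cytotoxic effector molecules went both ways, with 3 of 25 higher and 4 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.299). Gzmb and Ifng rose, whereas Ctsw (-0.98 ± 0.08), Gzmm (-0.85 ± 0.13) and Srgn (-0.39 ± 0.07) fell.

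Type I interferon response genes were lower in CD25hi in 24 of 29 cases and higher in 0 (26 and 1 adjusted over the list alone), with a median of -0.883 (camera adjusted p = 9.1e-24, or adjusted p = 0.00461 with an estimated correlation). The antiviral genes Ifit1 (7.23-fold), Ifit3 (6.54-fold), Oasl2 (4.88-fold) and Rsad2 (2.48-fold) were examples. The subunits of the type I interferon receptor, Ifnar1 (-1.20 ± 0.12) and Ifnar2 (-1.11 ± 0.12), fell too. Both are on the list of cytokine receptors other than CD25, of which 10 of 23 were lower and 3 higher (the same counts adjusted over the list alone, camera adjusted p = 0.000439, but adjusted p = 0.184 with an estimated correlation).

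Some genes of cell division were higher in CD25hi, Mki67 not among them. Of the DNA replication and S phase list, 13 of 34 were higher in CD25hi and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.362 (camera adjusted p = 1.98e-06, but adjusted p = 0.103 with an estimated correlation). The replication licensing factor Cdc6 rose by 0.93 ± 0.10, Mcm10 by 0.61 ± 0.07, the transcription factor E2f1 by 0.54 ± 0.07 and cyclin E1, Ccne1, by 0.57 ± 0.08. Of the G2 and mitosis list, 12 of 34 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 0.000308, and adjusted p = 0.0488 with an estimated correlation). The mitotic kinases Aurkb (0.79 ± 0.08), Nek2 (0.59 ± 0.08, probe sets from -0.217 to 1.14) and Cdk1 (0.44 ± 0.06) and the spindle protein Prc1 (0.50 ± 0.06) were among them.

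In each of the biosynthetic lists some members were called, most of them higher, but no list kept its call with an estimated correlation. For amino acid transport and ribosome biogenesis, 12 of 28 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 4.28e-05, but adjusted p = 0.0788 with an estimated correlation). The amino acid transporters Slc7a5 (1.17 ± 0.07) and Slc7a1 (0.56 ± 0.07) and the nucleolar genes Rrs1 (0.98 ± 0.12) and Npm1 (0.61 ± 0.09) rose. Of the endoplasmic reticulum chaperones, 11 of 24 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.00023, but adjusted p = 0.184 with an estimated correlation), including Creld2 (0.75 ± 0.10), Pdia6 (0.63 ± 0.09) and Sdf2l1 (0.60 ± 0.07). Cholesterol synthesis genes were higher in 7 of 20 cases and lower in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00602, but adjusted p = 0.184 with an estimated correlation). They included the enzymes Sqle (0.93 ± 0.13), Cyp51 (0.65 ± 0.08), Lss (0.64 ± 0.07) and Hsd17b7 (0.45 ± 0.08). Without probe sets that can match several transcripts Lss was not called (adjusted p = 0.058).

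The list of glycolysis and glucose uptake was not called (7 of 20 higher, 3 lower, 8 and 3 adjusted over the list alone, camera adjusted p = 0.114). It was called with only the CD25hi and CD25lo arrays (camera adjusted p = 0.0314) and without naive replicate 1 (camera adjusted p = 0.0379). Hexokinase 2, Hk2, rose 2.3-fold (1.20 ± 0.14), Pgam1 by 0.71 ± 0.12 and Tpi1 by 0.68 ± 0.11, while the kinase Pdk1 fell (-0.40 ± 0.06). Oxidative phosphorylation had 4 of 35 members higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.733). Uqcrfs1 rose (0.48 ± 0.08) and Cox6c fell (-0.34 ± 0.07). The list of IL-2 and STAT5 responsive genes, without Il2ra, was not called. It had 8 of 35 higher and 8 lower (9 and 8 adjusted over the list alone, camera adjusted p = 0.773). The alternative fry called this list lower (fry adjusted p = 0.0408), with a mean log2 difference of -0.049 and a median of 0.003. Cd83 alone can give that direction, so the call does not show that the list as a whole was lower. Osm (1.00 ± 0.09) and Xbp1 (0.42 ± 0.06) rose, and Cd83 (-2.71 ± 0.06) and Socs1 (-0.64 ± 0.09) fell.

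TCR-induced early genes were lower in 9 of 28 cases and higher in 3 (14 and 3 adjusted over the list alone, camera adjusted p = 0.00121, and adjusted p = 0.0375 with an estimated correlation). The transcription factors Irf8 (-1.48 ± 0.07), Egr2 (-1.67 ± 0.08) and Egr1 (-1.57 ± 0.20) fell. Among inhibitory receptors and their regulators, 9 of 14 were lower and 2 higher (9 and 3 adjusted over the list alone, camera adjusted p = 0.00136, and adjusted p = 0.0343 with an estimated correlation). Btla (-0.83 ± 0.10) and Tox (-0.91 ± 0.11) fell while Havcr2 and Cd244a (0.78 ± 0.11) rose. Of the chemokines, homing and adhesion list, 11 of 30 were lower and 4 higher (13 and 6 adjusted over the list alone, camera adjusted p = 0.00508, but adjusted p = 0.184 with an estimated correlation). The integrin Itgae (-2.31 ± 0.09), the follicle homing receptor Cxcr5 (-2.63 ± 0.33) and the chemokines Xcl1 (-1.33 ± 0.12) and Ccl4 (-0.96 ± 0.07) were lower. Apoptosis regulators had 8 of 27 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.0148, but adjusted p = 0.208 with an estimated correlation). These included genes of opposite action, the anti-apoptotic Bcl2 (-1.33 ± 0.20) and the pro-apoptotic Bcl2l11 (-1.25 ± 0.15) and Fas (-0.95 ± 0.07).

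**Figure D2:**
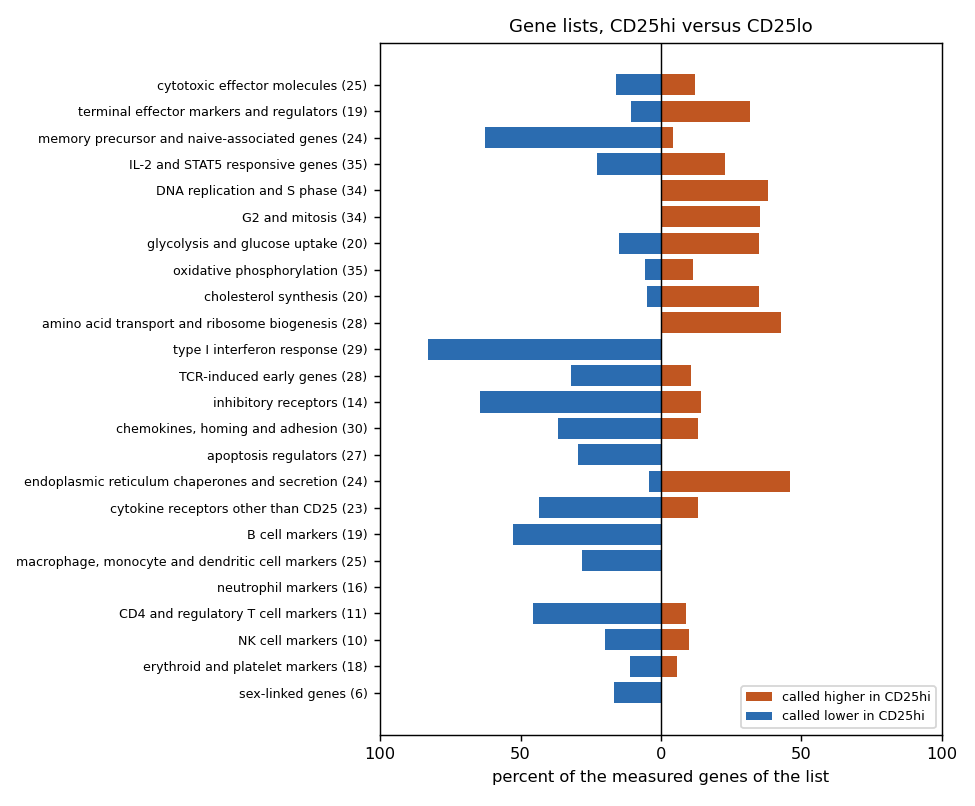
Share of the measured genes of each list called higher (right) or lower (left) in CD25hi than in CD25lo, in percent of the list, for 24 lists with the number of measured genes in brackets. The type I interferon list, with 24 of 29 members lower, and the memory precursor list, with 15 of 24 lower, extend furthest to the left among the T cell lists with over 20 genes.

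Markers of antigen-presenting cells moved in the same direction as the memory, interferon, TCR-induced, homing and inhibitory receptor lists. B cell markers were lower in CD25hi in 10 of 19 cases and higher in 0 (11 and 0 adjusted over the list alone, camera adjusted p = 2.84e-08, and adjusted p = 0.00272 with an estimated correlation), led by Cd74, H2-Aa, H2-Ab1 (-2.90 ± 0.08) and H2-Eb1. Markers of macrophages, monocytes and dendritic cells were lower in 7 of 25 and higher in 0, also adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.0254 with an estimated correlation). Tyrobp (-2.10 ± 0.11), Cst3 (-1.60 ± 0.07), Cd68 (-0.91 ± 0.09) and Fcgr3 (-0.71 ± 0.10) were among them. CD4 and regulatory T cell markers had 5 of 11 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0207, but adjusted p = 0.182 with an estimated correlation), including Izumo1r (-0.87 ± 0.10), Ctla4 (-0.72 ± 0.12) and Ikzf2 (-0.42 ± 0.08, probe sets from -0.884 to 0.159). Without probe sets that can match several transcripts this list was not called (camera adjusted p = 0.0922). Markers of NK cells (1 of 10 higher, 2 lower, camera adjusted p = 0.351), erythroid cells and platelets (1 of 18 higher, 2 lower, camera adjusted p = 0.932) and sex-linked genes (0 of 6 higher, 1 lower, Xist at -0.56 ± 0.10 with probe sets from -0.930 to 0.044, camera adjusted p = 0.701) were not called as lists, with the same counts adjusted over the list alone. The alternative fry called the NK cell list lower (fry adjusted p = 0.000269), with a mean of -0.188 and a median of -0.019. Tyrobp, which is also on the list of macrophages, monocytes and dendritic cells, can alone give that direction. Of 16 neutrophil markers limma called 0, also adjusted over the list alone (camera adjusted p = 0.932). An unadjusted p under 0.05 also gave 0, and the fit of only these groups called 1. With other-cell-type markers left out, an alternative added after the data were seen, 3646 genes differed, 24 of 28 interferon genes were lower and 15 of 23 memory genes were lower. This removed only the marker genes, not what admixed cells would add to the remaining genes, so it does not test admixture.

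The count of 3674 rested on a spread that included the noisier naive arrays. It was 7341 with only the CD25hi and CD25lo arrays, 7999 with array weights and 5537 without naive replicate 3. The balance of directions depended on this too, with 3821 higher and 3520 lower with only these arrays and 4293 and 3706 with array weights.

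The comparisons with naive cells asked what changed from day 0 to day 3.5 in each subset. Cell cycle genes were higher in both, as were the granzymes Gzmb and Gzmk and interferon gamma, whereas the perforin gene Prf1 stayed undecided. Its mean was not called in CD25lo (0.05 ± 0.07) or CD25hi (-0.08 ± 0.07), but its 2 probe sets were called in opposite directions, at -0.380 and 0.485 in CD25lo and at -0.541 and 0.387 in CD25hi. In CD25lo, Mki67, a marker of dividing cells, was 161-fold higher than in naive cells (7.33 ± 0.10), Ccnb2, a mitotic cyclin, 165-fold (7.37 ± 0.15), and Gzmb 83-fold (6.38 ± 0.12). In CD25hi these were 158-fold, 147-fold and 120-fold higher. Gzmk rose 93.3-fold in CD25lo and 92.6-fold in CD25hi, and Ifng 26.8-fold and 35.9-fold. The transcription factor Tbx21 rose 62.4-fold in CD25lo (5.96 ± 0.24) and 50.6-fold in CD25hi (5.66 ± 0.24). Il7r fell 6.23-fold in CD25lo (-2.64 ± 0.18) and 14.6-fold in CD25hi (-3.86 ± 0.18).

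In CD25lo, 13974 of 18193 genes differed from naive, 6768 higher and 7206 lower. The fit used 1 spread per gene for all groups, although naive arrays varied more (median SD 0.246, against 0.0976 in CD25lo and 0.0948 in CD25hi). Errors against naive are therefore likely too small, and calls too many, for both subsets. The lists of S phase and of G2 and mitosis had 34 of 34 members higher each, with medians of 2.47 (camera adjusted p = 4.47e-14, and adjusted p = 0.0412 with an estimated correlation) and 3.26 (camera adjusted p = 1.8e-18, and adjusted p = 0.00207 with an estimated correlation). The counts adjusted over the list alone were the same. Inhibitory receptors were higher in 10 of 14 cases and lower in 2, also adjusted over the list alone (camera adjusted p = 0.00136, and adjusted p = 0.0425 with an estimated correlation), including Pdcd1 (18.3-fold) and Havcr2 (15-fold). Type I interferon response genes were higher in 19 of 29 and lower in 3, also adjusted over the list alone (camera adjusted p = 0.00304, but adjusted p = 0.259 with an estimated correlation), with Oas3 at 8.73-fold and Mx1 at 5.72-fold. Cytotoxic molecules were higher in 16 of 25 and lower in 2, also adjusted over the list alone (camera adjusted p = 0.000504, but adjusted p = 0.0808 with an estimated correlation). Terminal effector markers were higher in 14 of 19 and lower in 1, also adjusted over the list alone (camera adjusted p = 2.59e-05, but adjusted p = 0.0706 with an estimated correlation). Memory and naive-associated genes went both ways, with 12 of 24 higher and 10 lower, also adjusted over the list alone (camera adjusted p = 0.873). Cd27 was 7.01-fold higher and Id3 3.02-fold higher, while Il7r and Il6ra (2.56-fold) fell.

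In CD25hi, 13633 genes differed from naive, 6466 higher and 7167 lower. S phase and G2 and mitosis genes were higher in 34 of 34 cases each, with medians of 2.87 (camera adjusted p = 1.29e-15, and adjusted p = 0.0307 with an estimated correlation) and 3.53 (camera adjusted p = 1.83e-19, and adjusted p = 0.00171 with an estimated correlation), and the same counts adjusted over the list alone. Memory and naive-associated genes were lower in 16 of 24 and higher in 5, also adjusted over the list alone (camera adjusted p = 0.00692, but adjusted p = 0.105 with an estimated correlation, and adjusted p = 0.053 with the probe set of largest interquartile range). B cell markers were lower in 16 of 19 and higher in 2 (camera adjusted p = 0.00307, but adjusted p = 0.0507 with an estimated correlation). B cells in the naive sort were not tested. Cytotoxic molecules were higher in 14 of 25 and lower in 2 (camera adjusted p = 0.00289, but adjusted p = 0.109 with an estimated correlation). Terminal effector markers were higher in 14 of 19 and lower in 1 (camera adjusted p = 3.67e-05, but adjusted p = 0.0636 with an estimated correlation), with the same counts adjusted over each list alone. Inhibitory receptors were higher in 9 of 14 and lower in 5, also adjusted over the list alone (camera adjusted p = 0.0385, but adjusted p = 0.105 with an estimated correlation). Without members shared with other cell types that list was not called (camera adjusted p = 0.17). Bach2 fell 6.74-fold, Dapl1 12.6-fold and the integrin gene Itgae 32.9-fold. Type I interferon response genes were higher in 12 of 29 and lower in 13, also adjusted over the list alone (camera adjusted p = 0.617), with Ifit3 11.5-fold lower. Cholesterol synthesis genes were higher in 19 of 20, also adjusted over the list alone (camera adjusted p = 1.1e-06, but adjusted p = 0.0543 with an estimated correlation), including Pmvk (12.1-fold) and Sqle (9.21-fold). In amino acid transport and ribosome biogenesis 23 of 28 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 3.67e-05, but adjusted p = 0.0792 with an estimated correlation), with Slc7a5 14.6-fold higher. Both lists rose in CD25lo against naive too. Cholesterol synthesis had 17 of 20 higher and 0 lower (camera adjusted p = 2.06e-05, 0.0781 with an estimated correlation). Amino acid transport had 20 of 28 higher and 2 lower (camera adjusted p = 0.00136, 0.167 with an estimated correlation).

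Both subsets shared 12375 genes changed from naive in the same direction, 5946 higher and 6429 lower. Independent lists of these sizes would share 2405 and 2839, and simulated unchanged groups set against the same naive arrays shared 307 on average over 100 simulations. No gene was changed in those simulations, so the 307 are false calls. They show that the fit calls too many genes against naive when naive arrays vary more. The fold changes correlated at 0.945 across genes, which are not independent replicates, against 0.932 in the simulations. Their covariance was 0.963 against a simulated 0.0343, a difference of 0.929. With 3 naive arrays the controls could not be split into parts of 2 or more, so part of the excess over the numbers for independent lists may come from the shared controls.

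Signal level moved with the difference from naive. Probe sets with a log2 level of 8 or more before centring had a median CD25lo minus naive difference of 0.465, against -0.280 for levels from 4 to 8 and -0.223 below 4. The class followed a probe set's level over the 11 arrays, 8 of them effector arrays. Sorting by it can by itself raise the difference among bright probe sets and lower it among dim ones. Markers of neutrophils fell in 15 of 16 cases in CD25lo and 14 of 16 in CD25hi (camera adjusted p = 0.000463 and 0.00043, adjusted p = 0.0393 and 0.0307 with an estimated correlation). The largest decreases in CD25lo included Psg28 (12.5-fold), Cyp2c54 (7.69-fold), the olfactory receptor gene Olfr64 (6.47-fold) and Lce1i (6.24-fold). Batch and group could not be told apart for naive and effector arrays, since no batch is labelled. The median of all genes was -0.0654 in CD25lo minus naive and -0.0819 in CD25hi minus naive.

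**Figure D3:**
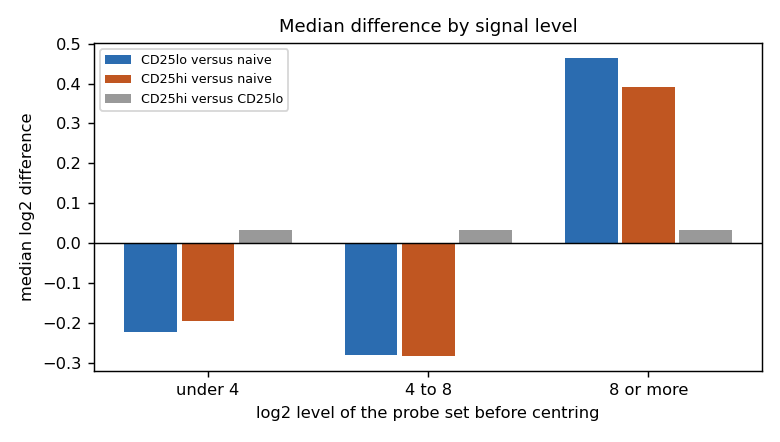
Median log2 difference over probe sets (vertical axis) by the class of signal level before centring (horizontal axis, log2) for the 3 comparisons. Bars for CD25lo versus naive run from -0.223 below 4 to 0.465 at 8 or more, and bars for CD25hi versus CD25lo stay between 0.0324 and 0.0340. The class comes from all 11 arrays, 8 of them effector arrays, so sorting by it can give part of the trend against naive.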

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

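The tests of B cells, macrophages and T cell expression, those of neutrophils and of erythroid cells or platelets in their present form, and the comparison by signal level were chosen after the result was seen. The tests of dendritic cells and of naive array contrast were set before their values were seen.

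Antigen-presenting cell transcripts were the clearest signal outside T cell biology, with MHC class II and Cd74 lower in CD25hi by a median of -3.17. Their values varied little between CD25lo arrays, with an SD of 0.03 for Cd74. B cells as the source of a change of that size are argued against by 15 other B cell markers. Of these, 6 were called lower and 0 higher, but their median was -0.234 and the lowest was -0.57, so a small share of B cells stays open. Cd79a and Ms4a1, chosen after their values were seen, were not called. For macrophages, 8 markers had a median of -0.00282, with limma calling 0 of them, 0 at an unadjusted p under 0.05 and 0 in a fit of only these groups. These 8 were picked after the values were seen. Cd68, Fcgr3, Tyrobp and Cst3, on the same fixed list but not among the 8, were called lower. The 8 markers therefore do not decide on macrophages. On the whole fixed list of macrophage, monocyte and dendritic cell markers, 7 of 25 were lower and 0 higher, with a median of -0.048. Dendritic cells in the CD25lo sort remain a candidate explanation. Of 32 dendritic cell markers not examined before, 22 were lower in CD25hi and 2 higher, with a median of -0.543. In every other setting 17 to 23 of these were lower. Tlr3 (-1.85 ± 0.11), Cadm1 (-1.26 ± 0.06), Wdfy4 (-1.44 ± 0.09), Ctsh (-2.42 ± 0.11) and Cd86 (-2.12 ± 0.08) were among the lower ones and Batf3 (0.62 ± 0.13) and Cd24a (0.84 ± 0.14) were the higher ones, all chosen after their values were seen.

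Of that list, 0 members stand on another list fixed here, and activated lymphocytes also express several of them, Batf3 and Cd24a included. A sort gated on CD8 may not remove dendritic cells, since a spleen subset of them carries CD8 alpha, although Cd8a itself decides little: its mean was lower in CD25hi (-0.39 ± 0.07), but 1 of its 5 probe sets was called and they ranged from -1.37 to 0.049. Expression by the CD25lo T cells themselves stays open too, and the SD of 0.03 does not decide between them, because bulk values do not show which cell made a transcript.

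Most genes differed from naive, with bright probe sets higher and dim ones lower in effectors. The level class came from all 11 arrays, 8 of them effector arrays, so sorting by it can give part of that pattern by itself. Lower contrast of the naive arrays stays open. In 128 genes that T cells do not use, such as olfactory receptors and keratin-associated proteins, the median CD25lo minus naive difference was -0.579 and 99 were called lower, but the signal level of their probe sets alone would give -0.223, which also meets the bound of -0.2, so the test decides nothing. The 26 of their probe sets at a level of 8 or more had a median of -0.976, against 0.468 for the others at that level. Some of these 26 may be dimmer, because the rule can class a dim probe set too high by chance. Whether level accounts for the decrease of these genes therefore stays open. Erythroid and platelet markers were lower than naive in 13 of 18 cases in CD25lo and 15 in CD25hi, and higher in 1 each. The list was called lower in both (camera adjusted p = 0.0124 and 0.00792, but 0.259 and 0.192 with an estimated correlation). In CD25lo their median lay 0.160 above that of the genes T cells do not use (95% bootstrap interval -0.0803 to 0.410). This argues against erythroid cells or platelets in the naive sort only as a source of a larger fall across the list. A small share of them stays open. Neutrophil markers had a median -0.237 from that of the genes T cells do not use (interval -0.530 to 0.138). Of these markers 15 of 16 were called lower, so neutrophils in the naive sort stay open. A change in RNA content per cell on activation is a biological alternative that was not tested, and batch and group cannot be told apart for naive arrays. Differences between CD25hi and CD25lo hardly share this pattern, with a median of 0.0676 for the same genes.

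Regrouping the arrays set each count against those of other splits. With 35 splits the real one can rank no better than 1 in 35, so chance is not excluded. Splits that mix the groups move their difference into the spread of the fit, which by itself lowers the counts of those splits. Of the 35 splits of the 8 effector arrays, only the real split (1 split) gave as many as 3674 genes, and the highest other count was 0. For changes of 2-fold or more, 1 of 35 splits reached 321 and the highest other count was 0. Among the 35 splits of the CD25lo and naive arrays 1 reached 13974, with 9485 as the highest other, and among those of the CD25hi and naive arrays 1 reached 13633, with 7716 as the highest other. Splits that mix naive with effector arrays thus still called many genes, and the cause was not tested.

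A set of 16 named genes moved in opposite directions from naive in the subsets, both changes being called, and the difference between the subsets was tested and called. Across all genes there were 124. In 15 of the 16, the gene was higher in CD25lo and lower in CD25hi than in naive. Their CD25hi minus CD25lo differences were -3.46 for Id3, -1.29 for Bcl6, -3.79 for Mpeg1, -3.49 for H2-Aa, -3.21 for H2-Eb1, -2.90 for H2-Ab1, -3.12 for Cd74 and -3.12 for Alox5ap. They were -3.11 for Rnase6, -2.10 for Tyrobp, -0.982 for Ctsw, -2.14 for Tnfrsf25, -2.85 for Ifit1, -1.57 for Egr1 and -0.835 for Btla. Cdh17 went the other way, at 1.72. H2-Aa, H2-Eb1, H2-Ab1, Cd74 and Tyrobp stand on fixed lists of antigen-presenting cell markers. Dendritic cells in the CD25lo sort remain a candidate source of such transcripts, so opposite changes within T cells were not shown for them. Errors against naive are also likely too small, so some of these calls against naive may be false. The 2 probe sets of Bcl6 disagreed in CD25lo against naive, at -0.269 and 1.05, both called. Its increase over naive in CD25lo was lost without naive replicate 1 (adjusted p = 0.146). Id3 was 1.60 ± 0.24 above naive in CD25lo and -1.87 ± 0.24 from naive in CD25hi, while the decreases of H2-Eb1 (-0.42 ± 0.15), Cd74 (-0.41 ± 0.07) and H2-Ab1 (-0.32 ± 0.09) in CD25hi were smaller than the -0.545 median of the genes T cells do not use and that of H2-Aa (-0.82 ± 0.09) was larger.

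Single arrays stood apart from the other 3 of their group in 33 of 414 groups of values, 7.97%, where chance gives about 1 in 20. The value is the gap to the nearest array as a share of the group's range. CD25hi replicate 2 stood apart for Tbx21 (0.932), Plbd1 (0.916), Ctsw (0.922), Creld2 (0.877), Pold1 (0.915) and Srebf2 (0.940), and for the means of the S phase (0.906), amino acid transport (0.890), endoplasmic reticulum chaperone (0.904) and cytokine receptor (0.878) lists. CD25hi replicate 1 did so for Mki67 (0.894), Rnase6 (0.864), Xbp1 (0.870), Gzma (0.936), Kdm5d (0.860) and the TCR-induced list (0.887), replicate 3 for Cdh17 (0.897) and replicate 4 for Fas (0.835). In CD25lo, replicate 2 stood apart for Cd44 (0.840), Igfbp4 (0.922) and Cd40lg (0.842), and replicate 3 for Tbx21 (0.883), Socs1 (0.889), Ndufa1 (0.877), Camp (0.909) and Epor (0.937). CD25lo replicate 4 did so for Ndufc1 (0.868), Lss (0.888), Manf (0.842), Il12rb1 (0.980), Cd22 (0.846), the IL-2 and STAT5 list (0.996) and the TCR-induced list (0.868).

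Outside the genes reported, 1073 of 10092 probe sets that name several genes or are not listed in the annotation used differed between CD25hi and CD25lo in a fit of all probe sets.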

How the results depend on the processing

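Alternatives with the level class, other-cell-type markers and list members shared with other cell types were chosen after seeing the data. The count of 3674 genes between CD25hi and CD25lo rose to 7341 with only these groups, holding all 3674, and to 7999 with array weights and 6977 with the replicate number as a block over the 8 effector arrays. The naive arrays' wider spread enters the main estimate and is left out or weighted down in these. Replicate numbers gave no sign of pairing: deviations of same-numbered CD25lo and CD25hi arrays correlated at 0.0169, -0.114, 0.013 and 0.0439. Not every array correlated best with its own number. These values do not exclude that same-numbered arrays came from the same mice or sorts. With the block over all 11 arrays the counts were 3207, 13618 and 13267 for CD25hi against CD25lo, CD25lo against naive and CD25hi against naive. Genes changed by 2-fold or more rose from 321 to 606 with the probe set of largest interquartile range and 592 with every probe set. The former takes the probe set that varies most over the 11 arrays and the latter that with the lowest p, in place of a mean. Leaving out 1 array gave 2793 to 5537 genes for CD25hi against CD25lo, the highest without naive replicate 3, and 305 to 354 at 2-fold or more. It gave 13281 to 14320 for CD25lo against naive, 13016 to 13991 for CD25hi against naive and 11851 to 12739 shared by both. Split by direction, the 1670 higher and 2004 lower genes became 3821 and 3520 with only these groups, 3615 and 3362 with the block over 8 arrays, 4293 and 3706 with array weights and 2696 and 2841 without naive replicate 3. At 2-fold or more, CD25lo against naive went from 4458 to 7397 with the probe set of largest interquartile range and 7483 with every probe set, and CD25hi against naive from 4445 to 7154 and 7225. Other totals of called genes stayed within 1.5 times the main ones, and centring each array moved the shares of higher calls by under 10 percentage points, from 48.4% to 52.4% in CD25lo against naive.

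With the probe set of largest interquartile range, Prf1 in CD25lo against naive turned to -0.38 and in CD25hi against naive was called lower (-0.541, adjusted p = 0.00493), Cd8a in CD25lo against naive to 0.47 and Il15ra in CD25hi against naive to 0.47. The probe sets of these genes disagree. In CD25lo against naive fry gave the opposite direction to camera for B cell markers (mean 0.337) and for macrophage, monocyte and dendritic cell markers (mean 0.240), and in CD25hi against naive for NK cell markers (mean 0.136). In these 3 lists the mean was positive and camera, which did not call them, gave a lower direction, with medians of -0.314, -0.406 and 0.035. The increase of Bcl6 over naive in CD25lo (0.39) was not called without naive replicates 1 (adjusted p = 0.146) or 2 (0.123) or without CD25lo replicates 2, 3 or 4 (0.0542 to 0.0705) or with only these groups (0.0689). That of Eomes (0.80) was not called without naive replicates 2 (0.227) or 3 (0.146) or any of the 8 effector arrays (0.0551 to 0.0797) or with only these groups (0.0947), and with the probe set of largest interquartile range it fell to 0.189 (adjusted p = 0.649). Between CD25hi and CD25lo, Tbx21 (adjusted p = 0.0414) and Eomes (adjusted p = 0.019) were called without naive replicate 1. With an estimated correlation 8 of the list calls between CD25hi and CD25lo were lost, 12 in CD25lo against naive and 11 in CD25hi against naive. Quantile normalization, a mean-level filter and an RNA quality covariate were not run. Signal over background could not be given because levels were removed by centring.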

Other observations

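The bounds for the ATF4 list and for the correlation were set before their values were seen. The count of genes by which subset naive was nearer to, the correlation over called genes, the ATF4 count without list members and the ATF4 counts in other settings were chosen after.

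Mt2, Nsg2 and Tdrp stand on none of the fixed lists. Mt2 was 5.19-fold higher in CD25hi than in CD25lo (2.38 ± 0.09), and Nsg2 was 11-fold lower (-3.47 ± 0.10). Tdrp was 49.6-fold lower in CD25hi than in naive cells and 8.27-fold lower in CD25lo. Itgax, an integrin on the homing list and on the macrophage and dendritic cell list that effector CD8 T cells also express, was 52.8-fold higher in CD25lo and 30.3-fold higher in CD25hi than in naive cells.

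Asns and Slc7a3 were among the genes raised most in CD25hi, and a stronger ATF4 amino acid response was a hypothesis for this. Of 29 ATF4 target genes, 7 were called higher in CD25hi and 1 lower, with a median of 0.127, which neither met the bound set for this hypothesis (40% higher and a median of 0.15) nor ruled it out (under 20% higher). The count depended on the setting: 2 were higher and 0 lower without CD25lo replicate 4 or CD25hi replicate 4, 11 and 4 with only these groups, and 13 and 5 with array weights, or 6.9% to 44.8% higher. On lists fixed here and tested before stood 4 of them, and of the other 25, 6 were higher and 0 lower, with a median of 0.149, but 2 and 0 without CD25lo replicate 4 and 12 and 4 with array weights. The hypothesis stays open. Cth (0.60 ± 0.08) and Psat1 (0.74 ± 0.12) rose in every setting that held them. The lower gene was Ddit3 (-0.52 ± 0.14), not called with the probe set of largest interquartile range (adjusted p = 0.151) or when any 1 of 5 effector arrays was left out (0.0509 to 0.0712). All 3 were chosen after their values were seen.

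CD25lo being less far along the change from naive was another hypothesis. It predicts that across genes CD25hi minus CD25lo runs against naive minus the mean of both subsets. The correlation was -0.115 (Spearman -0.0201), across genes that are not independent replicates, and 19 of the 35 splits of the 8 effector arrays gave one as large in size, up to 0.362. The correlation therefore does not decide it. Over the genes called between the subsets it was -0.383, in the predicted direction. Of the 1670 genes higher in CD25hi, 86.7% had a naive mean nearer to CD25lo, and of the 2004 lower ones 32.2% did. Naive lay below the mean of both subsets in 76.4% of these genes, which by itself shifts these shares in opposite directions, so the hypothesis stays open.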
